A study of Mus musculus with 3 samples.

How the data were processed

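Messenger RNA of mouse embryonic stem cells lacking Tet1, Tet2 and Tet3 (J1 background) was measured by bisulfite sequencing in 3 samples of 1 group. Per the labels' protocols, the cells were grown on mouse embryonic fibroblast feeders, the feeders were depleted by repeated plating, and polyadenylated RNA was selected from total RNA, fragmented, treated with DNase, converted with bisulfite and sequenced as paired-end reads. Bisulfite turns unmodified cytosine into uracil, which is read as thymine, while 5-methylcytosine and 5-hydroxymethylcytosine stay cytosine. The reads therefore do not separate these 2 modifications from each other or from cytosines that the reagent failed to convert. Nothing in the labels says whether the samples came from separate cultures, so any spread between them may be technical. The p-values of single cytosines set reads against the background of their library as if each read were independent, and no spread between samples enters them.

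Per the submitters' processing notes, BSMAP was used and the genome build was mm9; no version, counting step or annotation is given in the sources used here. The deposited tables hold, for each cytosine of a RefSeq mRNA, its position along the transcript, the coverage as a raw read count, and the unconverted share as a fraction of that count. The authors listed no cytosine with a coverage below 3, and all 15021 transcript identifiers are protein-coding (NM) accessions, so mitochondrial, ribosomal, transfer and non-coding RNAs are not analysed here. Of these identifiers, 14932 were matched to a gene symbol by accession without version, using an annotation of GRCm38.p6 for names only. Genomic coordinates and the place of a site in exon, coding sequence or untranslated region are not used here, because that annotation is of another build than mm9 and no sequence was at hand. Positions are those of the tables, whose lowest value is 1.

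The unconverted share times coverage was whole, within 1e-06, at 100% of the listed cytosines, and the product was taken as the number of unconverted reads. The authors' tables split reads among transcript models: of the 8 listed Eif5a transcripts, none had a listed cytosine beyond position 321. Reads common to several models thus appear to be missing, as in the 1433 genes with more than 1 listed transcript, and low coverage of such a gene does not mean low expression. Coverage summed over cytosines counts a read once for each cytosine it spans. It was 151362866, 142608298 and 139884444 in replicates 1, 2 and 3.

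The background was the library-wide unconverted share. A cytosine was testable with a coverage of at least 10 in all 3 libraries (1639820 cytosines in 9395 transcripts of 9002 named genes). In each library, the unconverted reads were set against the background by a one-sided exact binomial test. The 3 p-values were combined by Fisher's method and adjusted by Benjamini-Hochberg over all testable cytosines. A candidate methylated site had an adjusted p below 0.05, a mean unconverted share of at least 10%, and a share above the background in each library. The median testable coverage was 33, 30 and 29 reads, at which a count of 0 allows a share (3 counts of the total) of up to 9.09%, 10% and 10.3%; at the minimum coverage of 10 reads it allows 30%. These limits and all intervals cover counting error only, since reads copied by PCR carry no molecular identifiers.

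Tests of gene lists and of cytosine spacing used Fisher's exact test over cytosines (two-sided) with Benjamini-Hochberg adjustment over 12 lists or 2 spacings. Neighbouring cytosines share reads, so these p-values are too small where candidates lie together. Each list's median gene-level unconverted share was ranked among 10000 random lists of equal size matched on coverage decile, and clustering was compared with 1000 coverage-matched draws. Lists were fixed before the data were examined, as were the calling rule, the coverage and level minimums and the choice of named sites. S6 kinases and the S19-binding protein, which share a prefix with the ribosomal proteins, were left out of that list. Named were the 20 candidates with the highest mean share, the 10 genes with the most candidates, the 10 genes with the largest coverage, the Tet genes, and up to 4 genes with a candidate per list; other names were chosen after their values were seen, and the text says so. Some genes that this rule selects are not reported here.

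Planned comparisons of mitochondrial with nuclear transcripts, of CG, CHG and CHH contexts, and of transcript regions were not run, for want of such transcripts, sequence or annotation. For the same reason the motif test used only the spacing of listed cytosines that a motif requires. For CTCCA this is a cytosine at +2 and +3 and none at +1 and +4 from the site; for CNGGG it is none at +2, +3 and +4. Of 1135219 listed cytosines just downstream of testable ones, 77 had a best-library coverage below 5, so few can have fallen below the listing minimum.

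The calling was tested on simulated data with the real coverage of 1639820 cytosines and 200 altered ones. With a plain binomial background it recovered 32% of sites set at 10%, 88% at 20% and 100% at 50% and 90%, with 0 false candidates. With a background that varied between cytosines as fitted to the data (beta-binomial), drawn separately for each library, the same rule gave 13 false candidates. Differences between cytosines that the libraries share were not simulated, so 13 may understate the false candidates. Alternatives covered the coverage and level minimums, Poisson and beta-binomial tests, a local background within 100 nt, the highest of the 3 p-values, Bonferroni adjustment, isolated candidates alone, and leaving out each replicate. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.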

Results

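The data comprised bisulfite-converted mRNA from 3 samples of Tet1, Tet2 and Tet3 triple-knockout mouse embryonic stem cells. Tet enzymes oxidise 5-methylcytosine. The samples form 1 group of 3 and no wild-type sample was analysed here, so the comparisons are between cytosines, transcripts and gene groups within these libraries. Replicates 1, 2 and 3 listed 3846960, 3658396 and 3653533 cytosines in 13937, 13892 and 13654 transcripts, with a median coverage of 11, 10 and 10 reads.

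Nearly all cytosines of the measured mRNAs were converted. The unconverted share over all reads was 1.53% in replicate 1, 1.45% in replicate 2 and 1.41% in replicate 3, a mean of 1.46% ± 0.0643 (SD, n = 3). The counting interval of each library was narrow (95% Wilson interval of replicate 1, 1.531% to 1.535%). It takes every count as independent, although a read counts once for each cytosine it spans. The interval is therefore too narrow to judge the spread between libraries. At 74.9%, 76.4% and 77.1% of the listed cytosines, no unconverted read was seen. The share hardly moved with coverage, from 1.49% ± 0.0632 at a mean coverage of 10 to below 20 reads to 1.45% ± 0.0634 at 100 reads or more (SD, n = 3).

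The 3 knocked-out genes were read first. Tet1 (NM_001253857.1) had 17.7 ± 1.53 listed cytosines per library (SD, n = 3), all between positions 4666 and 4774 of the transcript, with a mean coverage of 7.52 ± 0.973 reads. Tet2 (NM_001040400.2) had 668 ± 45.6 listed cytosines between positions 46 and 9067, at 11.2 ± 0.679 reads. Tet3 (NM_183138.2) had 380 ± 59.2 listed cytosines between positions 276 and 10570, at 6.11 ± 0.0436 reads, and its longest stretch without a listed cytosine ran from 1154 to 2560. The deleted exons are not given in the sources used here, so neither the reads over Tet2 and Tet3 nor the few over Tet1 check the knockout. Coverage of cytosines is only a rough measure of transcript abundance. None of the 199 testable cytosines of the 3 genes was a candidate in the binomial test, with an exact 95% upper limit of 1837 per 100000. The Poisson and beta-binomial tests also gave 0, and 3 of the 199 had an unadjusted combined p below 0.05. Their unconverted share of 1.38% ± 0.384 differed from that of the other genes (1.46% ± 0.0637) by less than its own spread.

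Which cytosines stayed unconverted above the background in all replicates was asked next. Of 1639820 testable cytosines, 8189 had an adjusted p below 0.05 in the combined binomial test, and 7320 of these had a mean share below 10%. The rule left 775 candidates in 600 transcripts of 599 named genes. Most were weak: 689 lay at 10% to 20%, 71 at 20% to 50%, and 15 at 50% or above, with a median of 12.9%. Of the 775, only 441 had an unadjusted p below 0.05 in the one-sided binomial test of each of the 3 libraries. A single candidate was found in 503 genes, and 96 genes held several. A coverage minimum of 20 reads gave 489 candidates, and testing the highest of the 3 p-values in place of their combination gave 109.

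Several of the candidates with the highest share lay in mRNAs of ribosomal proteins. Position 241 of Rpl26 (NM_009080.2) was unconverted in all 74 reads of the 3 libraries, and position 19 of Rplp2 (NM_026020.6) in all 41 reads. Position 153 of Rpl34-ps1 (NM_001199350.1), a model closely related to the ribosomal protein gene Rpl34, was unconverted in 201 of 202 reads, and position 703 of Rps2 (NM_008503.5) at 77.9% ± 3.23 (SD, n = 3). These genes have near-identical copies, so the origin of their reads is uncertain, and the same holds for position 369 of the polyubiquitin gene Ubb at 85.3% ± 9.64. At Rpl26 the coverage fell from 74 reads at the site to a median of 4.5 and 3 reads at 50 to 100 nt on either side, while it reached 2637 reads elsewhere in the transcript.

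The other mRNAs with a candidate at 50% or above came from 10 genes. Srsf6, a splicing factor, had 80.2% ± 9.90 at position 1251 and Brip1, a DNA helicase, 77.8% ± 5.45 at position 4231. Tmod3, which caps actin filaments, had 76.1% ± 2.46 at position 3560, Trio, a guanine nucleotide exchange factor, 75.0% ± 5.46 at position 197, and Trim41, a ubiquitin ligase, 70.0% ± 1.26 at position 111. The basement membrane gene Nid2 followed with 59.8% ± 4.20 at position 521, Ccdc107 with 59.2% ± 19.4 at position 400, Rab4b, a small GTPase of endosomes, with 56.0% ± 6.40 at position 362, Mfsd11 with 54.0% ± 10.1 at position 2933, and Septin1 with 52.0% ± 5.33 at position 1222 (SD, n = 3 for each). Srsf6 had 55 reads at its site and up to 18264 elsewhere in the transcript. Brip1 fell from 359 reads at its site to medians of 8 and 0 at 50 to 100 nt on either side. In Tmod3, Trim41 and Rab4b, coverage on both sides was also below 0.5 times that at the site. In Srsf6, Trio, Nid2, Ccdc107, Mfsd11 and Septin1 it was not.

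Below 50%, the next sites included the most deeply read one of the 20 highest, whose mean coverage lay between 13.7 and 462 reads. Nus1 (NM_030250.2), a subunit of the enzyme that makes dolichol precursors, was unconverted in 583 of 1386 reads at position 473, or 42.2% ± 2.86 (SD, n = 3). Cenpv had 47.2% ± 1.14 at position 680 from 492 reads, and Sec61a1, the pore of the endoplasmic reticulum translocon, 40.1% ± 6.39 at position 2857 from 334 reads. Polr2f, a subunit shared by the RNA polymerases, had 42.6% ± 3.99 at position 237, next to other candidates. These 4 sites and the 15 at 50% or above were also called with the highest of the 3 p-values.

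**Figure D1:**
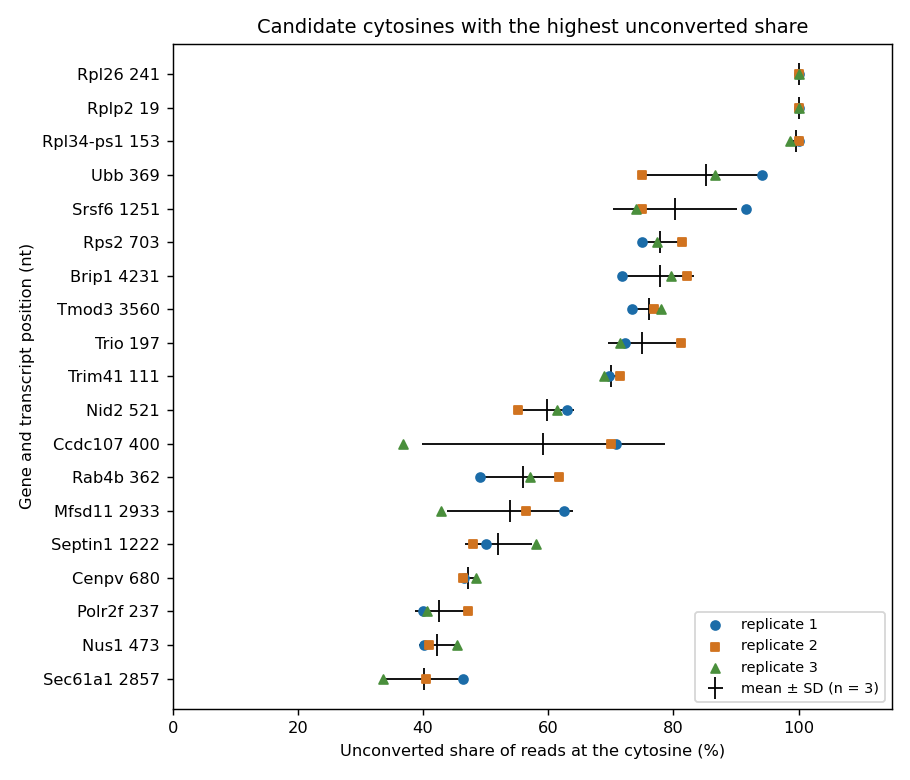
Unconverted share of reads (%, x axis) at 19 of the 20 candidate cytosines with the highest mean, named by gene and transcript position (y axis); symbols are the 3 replicates, and black marks are the mean ± SD. Cenpv and Trim41 vary little between replicates (SD 1.14 and 1.26), while Ccdc107 varies widely (SD 19.4).

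Some mRNAs carried many candidates, in part as runs of neighbours. Ppp1r14b, an inhibitor of protein phosphatase 1, held 13 candidates between positions 22 and 308, with shares from 10.1% to 16.1%. Hnrnpa0, an RNA-binding protein, and Slc30a5, a zinc transporter, held 9 each. Those of Hnrnpa0 were spread from position 29 to 1214, while those of Slc30a5 lay within positions 281 to 306 and reached 37.6% ± 9.96 (SD, n = 3). Rcc2 had 8 candidates spread from 250 to 2823, the scaffold gene Slc9a3r1 had 7 between 205 and 225, and Lrpprc, which binds mitochondrial mRNAs, had 5 between 314 and 326. Polr2f, Rad23b (a DNA repair factor) and Rsad1 had 6 each. Of all 775 candidates, 147 had another candidate within 10 nt. In 1000 coverage-matched random draws the share of such sites averaged 0.288% and reached 1.29% at most, so the permutation p of 0.000999 is the smallest these draws can give. The draws took cytosines singly, whereas cytosines within 10 nt share reads. A few unconverted molecules can thus yield several neighbouring candidates, and this p does not tell what causes the runs.

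**Figure D2:**
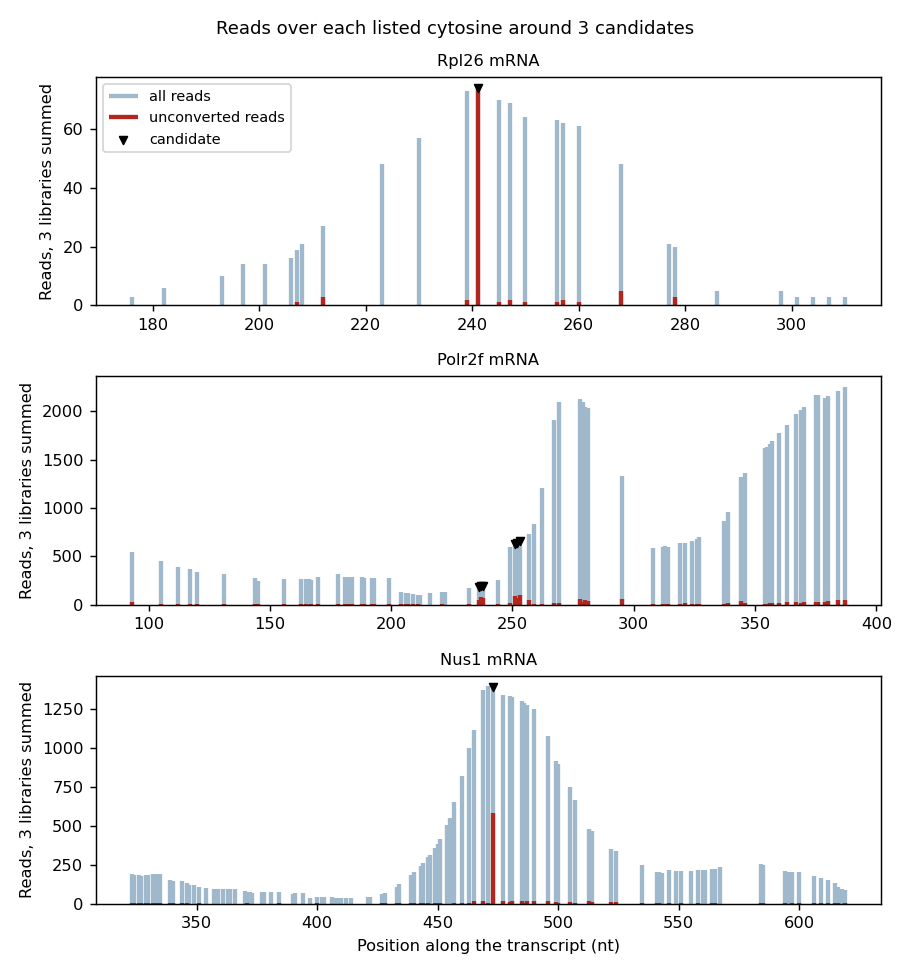
Reads over each listed cytosine (y axis, 3 libraries summed, linear from 0) along 3 transcripts (x axis, position in nt), with unconverted reads in red and candidates marked by triangles. Rpl26 (position 241) and Nus1 (position 473) each have 1 candidate in the stretch drawn, and Polr2f has 6 candidates from 236 to 253.

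The 10 most deeply covered genes held 2 candidates among 3822 testable cytosines, or 52.3 per 100000 (exact 95% interval 6.34 to 188.9), close to the 47.3 of all testable cytosines. Eef2, the elongation factor that moves the ribosome, took 1.04% ± 0.0109 of all coverage (SD, n = 3) and had 1 candidate among 855 testable cytosines, at position 691 with 11.1% ± 1.86. Trim28, a chromatin corepressor, had 1 candidate among 928, at position 528 with 10.2% ± 3.38. The other 8 genes of the 10 with the largest coverage had 0, among them the ribosomal protein genes Rplp0, Rps12, Rpl23 and Rpl41, the chaperone gene Hsp90ab1 and the elongation factor gene Eef1a1. The Poisson and beta-binomial tests gave 0 in these genes as well, while 26 cytosines of Rpl41 to 91 of Hsp90ab1 had an unadjusted combined p below 0.05, none at 10% or above. The gene-level unconverted shares of the genes named here ran from 1.32% ± 0.0683 in Hsp90ab1 to 1.65% ± 0.0677 in Trim28 (SD, n = 3). Per 100000 testable cytosines, candidates numbered 37.0 at a mean coverage of 10 to below 20, 69.8 at 20 to below 50, 25.8 at 50 to below 100 and 28.6 at 100 or more. Candidates at 20% or above numbered 7.32, 4.20, 5.15 and 4.21 in the same order. Cytosines with an adjusted p below 0.05 at any level numbered 50.1, 155, 441 and 2412, so the level minimum of 10% removed most of them at high coverage.

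Gene lists fixed beforehand were then compared with all other cytosines. The 87 testable genes of cytosolic ribosomal proteins held 18 candidates in 11 genes, 140 per 100000 cytosines (exact 95% interval 82.9 to 221) against 46.5 elsewhere. The odds ratio was 3.01 (adjusted p = 0.000741, Fisher's exact test over cytosines), and 4.69 within coverage strata, a comparison chosen after seeing the data. Besides Rpl26, Rplp2, Rpl34-ps1 and Rps2, they included Rpl18, whose position 306 reached 36.2% ± 1.86 at a mean coverage of 260 reads (SD, n = 3), and Rpl7l1, a paralogue of Rpl7 with 4 adjoining candidates from 713 to 716, both named after their values were seen. Without Rpl7l1, a choice made after seeing the data, the odds ratio was 2.41 (adjusted p = 0.0174, Fisher's exact test). The ribosomal call was lost at a coverage minimum of 20 reads (odds ratio 2.10, adjusted p = 0.110) and among candidates without a neighbour (2.25, adjusted p = 0.231), by the same exact test. The odds ratio rose to 9.48 at a level minimum of 20% (adjusted p = 0.000772, exact test) and to 17.1 with the highest of the 3 p-values (adjusted p = 5.97e-11, exact test). The sites in Rpl26, Rplp2, Rpl34-ps1 and Rps2, whose reads are of uncertain origin, count under both settings. Rpl26, Rplp2, Rpl34-ps1 and Rps2 held 1, 2, 1 and 4 of the 18 candidates of the list, and Rpl7l1 held 4 more. The list was not tested without the genes of uncertain read origin. The odds ratios above may therefore rest on these few genes and do not show a trait of ribosomal protein mRNAs in general. Over the 9 alternatives run for the list, the adjusted p of these exact or stratified tests ran from 5.97e-11 to 0.231. Over all reads, the list stood at 1.45% ± 0.0669 against 1.46% ± 0.0631 in other genes, and its gene median ranked at the 51.6th percentile of matched random lists.

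The list of RNA cytosine methyltransferases and m5C readers held 6 candidates in 3 of 7 testable genes, with an odds ratio of 6.23 (adjusted p = 0.00301, Fisher's exact test). Alyref, an mRNA export factor that binds m5C, had 4 of them between positions 147 and 188, the highest at 15.8% ± 0.979 (SD, n = 3). Nsun2, an mRNA and tRNA m5C methyltransferase, had 15.7% ± 1.35 at position 1952, and Nop2, a methyltransferase of ribosomal RNA, 10.3% ± 2.10 at position 471. This call was lost among candidates without a neighbour (odds ratio 3.83, adjusted p = 0.273) and without replicate 3 (4.11, adjusted p = 0.106), by the same exact test, and no member had a candidate at 20% or above. The odds ratio was 22.6 with the highest of the 3 p-values, a setting that left only 109 candidates in all genes together. Over the 8 alternatives run for the list the exact or stratified adjusted p ran from 1.28e-06 to 1. The list was not tested without Alyref, so its odds ratio may rest largely on that mRNA.

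In the other lists no difference passed the test. Pluripotency genes held 3 candidates in 19 testable genes (40.8 per 100000, exact 95% interval 8.41 to 119): Lin28a, an RNA-binding protein of stem cells, with 25.7% ± 3.86 at position 3306, Tdgf1 with 14.1% ± 3.95 at position 554, and Tfcp2l1 with 13.9% ± 7.81 at position 626 (SD, n = 3). Pou5f1 and Sox2 had 0 among 154 and 535 testable cytosines, and Nanog and Esrrb had no testable cytosine (these 4 were named after their values were seen). A lack of testable cytosines does not mean low expression. Glycolysis genes held 3 candidates, in Pfkp (21.7% ± 4.41 at position 1726), Eno1 (13.3% ± 9.13 at 1550) and Pfkl (11.1% ± 1.22 at 1494). Cytoskeletal genes held 2, in Actb (15.9% ± 5.97 at position 1744) and Cfl1 (12.6% ± 1.78 at 106), and translation factors held the 1 in Eef2. Chaperones had 0 of 6108 testable cytosines, with an exact 95% upper limit of 60.4 per 100000, above the 47.4 of other genes. Replication-dependent histones, early differentiation markers and imprinted genes had 0 of 579, 1444 and 2382, with exact 95% upper limits of 635, 255 and 155 per 100000. At an unadjusted combined p below 0.05 there were 575 chaperone, 22 histone, 51 differentiation and 58 imprinted-gene cytosines, and the Poisson and beta-binomial tests gave 0 candidates in each of these lists.

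Fibroblast markers, chosen for the feeder cells, took 0.0647% ± 0.0109 of all coverage, against 0.0691% ± 0.00238 for early differentiation markers and 0.948% ± 0.0179 for the pluripotency genes (SD, n = 3). Coverage is only a rough measure of transcript abundance, and which cells these transcripts came from was not tested. The list held 1 candidate, at position 1165 of the collagen gene Col1a1 with 20.7% ± 1.72. The unconverted share of the list was 1.54% ± 0.103, higher than that of other genes in each of the 3 libraries, with its gene median at the 91.1st percentile of matched lists. The same held in all 3 libraries for early differentiation markers (1.53% ± 0.0434, percentile 88.0), histones (1.55% ± 0.158, percentile 87.5) and methyltransferases and readers (1.64% ± 0.0858, percentile 74.3). Other lists were lower in all 3 libraries: pluripotency genes (1.40% ± 0.0600, percentile 18.1), chaperones (1.39% ± 0.0658, percentile 41.3) and cytoskeletal genes (1.40% ± 0.0568, percentile 23.0). So were translation factors (1.44% ± 0.0631, percentile 67.8) and ribosomal proteins. An exact sign-flip test over 3 libraries cannot give a p under 0.25.

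**Figure D3:**
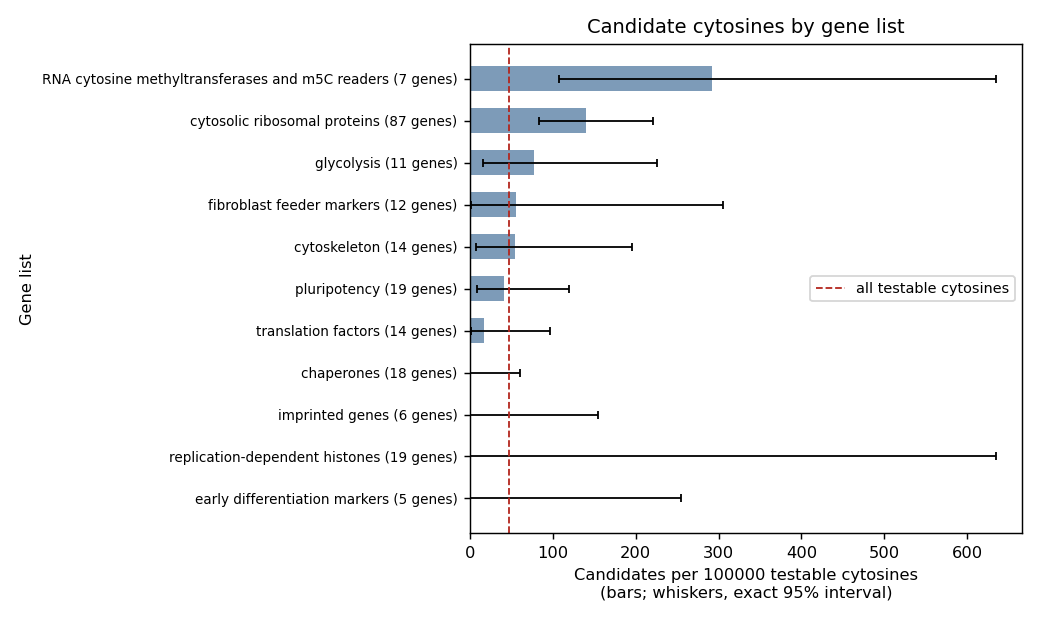
Candidates per 100000 testable cytosines (x axis, linear) in each gene list with testable cytosines (y axis, number of genes in brackets); bars are the rate, whiskers the exact 95% binomial interval, and the dashed line the rate over all testable cytosines. The Tet genes (0 of 199) are left out for their wide interval; only the ribosomal protein list and the methyltransferase and reader list have intervals above the line.

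The spacing of cytosines around the candidates was compared with the motifs of mRNA methyltransferases. The spacing that CTCCA, the motif of NSUN6, requires was found at 16 candidates (2.06%) and at 3.84% of other testable cytosines, an odds ratio of 0.528 (95% interval 0.322 to 0.866, adjusted p = 0.00847, Fisher's exact test). The spacing that CNGGG, a motif of NSUN2, requires was found at 373 candidates (48.1%) and at 42.7% of the others, an odds ratio of 1.246 (95% interval 1.08 to 1.43, adjusted p = 0.00510, the same exact test). Many other sequences have these spacings, so the counts do not show the motifs themselves. At a coverage minimum of 20 reads neither difference passed the test (adjusted p = 0.0675 for both, exact test). The CNGGG odds ratio was 2.05 at a level minimum of 20%. Over the 7 alternatives run for each spacing the adjusted p of the exact test ran from 0.00105 to 0.775 for CTCCA and from 0.000248 to 0.0675 for CNGGG.

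Agreement between the replicates was low across all cytosines and higher at the strong candidates. Across all cytosines with a coverage of at least 10 in both libraries, Pearson's r between libraries was 0.0859 to 0.0900 and Spearman's rho 0.146 to 0.151; cytosines are not independent replicates. At a coverage of at least 50 in both, r was 0.264 to 0.268 and rho 0.181 to 0.184. Across the 86 candidates at 20% or above, r was 0.826 to 0.839 and rho 0.436 to 0.553. Across the 689 at 10% to 20%, r was -0.253 to -0.205 and rho -0.252 to -0.215. Both sets were chosen on the mean of the same libraries, which by itself moves these values. Called in 1 library alone, 550, 620 and 559 cytosines passed in replicates 1, 2 and 3. Of these, 96 were shared by all 3 libraries, against 7.09e-05 for independent lists. That expectation gives every cytosine the same chance of a call, whatever its coverage. The overlap therefore cannot separate methylation from stable differences in conversion between cytosines. Sites were also chosen in 2 libraries and read in the one left out. Those chosen at 20% or above averaged 26.4% ± 0.703 there, and those chosen at 10% to 20% averaged 7.60% ± 0.375, against a background of 1.46% (SD, n = 3 libraries left out in turn).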

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

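All tests in this part were chosen after the result was seen, except those on runs of neighbouring candidates and the beta-binomial count, which were planned; the pseudogene test at 20% to 50% was set after the pattern was seen but before its own result. Cytosines read to the minimum in only 2 libraries (317800 in all) were outside the comparisons. The rule applied to those 2 libraries called 106 of them at 10% or above, of which 2 stood at 50% or above, with no control samples to set them against. Position 365 of Ppia, the cyclophilin A gene, was unconverted at 100% in all 20 reads of replicates 2 and 3 and in all 7 reads of replicate 1. Position 2011 of Fam83a was unconverted at 72.7% in replicates 1 and 3 (16 of 22 reads) and in 7 of 8 reads of replicate 2.

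The first pattern is near-complete loss of conversion at single cytosines. Of the 15 genes with a site at 50% or above, 5 (Rpl26, Rpl34-ps1, Rplp2, Rps2 and Ubb) have a pseudogene named after them, or are one, against 0.915 on average in coverage-matched draws (permutation p = 0.002, 1000 draws), but these genes prompted the idea and cannot bear it out. Reads shared with pseudogenes may still act here: where a copy carries thymine, a converted read could match both and be dropped, while an unconverted one matches the gene alone. The same test on the 63 genes with a highest site at 20% to 50% gave 4 with such a pseudogene against 3.10 (permutation p = 0.370), and islands of coverage, a mark of selective loss of converted reads, held 6 of the 15 sites against 3.88 in matched draws (permutation p = 0.156), so neither decides. Both explanations stay open, and no biological explanation was tested, since the design holds 1 group.

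The second pattern is the runs of candidates in Ppp1r14b, Slc30a5, Slc9a3r1 and others. If a stretch of RNA escaped the reagent as a whole, its other cytosines should be raised too. Those within 10 nt of clustered candidates were unconverted 2.36 ± 0.0878 times as often as all other testable cytosines (SD, n = 3 libraries), past the bound of 2 set beforehand, which is consistent with local incomplete conversion. Around isolated candidates the ratio was 1.59 ± 0.0406, below that bound but above the one set for no effect, so local incomplete conversion may account for part of these as well. No biological explanation, such as closely spaced methylated cytosines, was tested.

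The third pattern is the mass of weak candidates at 10% to 20%. Chance excess in single libraries as the whole cause is argued against by the library left out, where sites chosen at this level stood at 5.19 ± 0.0829 times the background (SD, n = 3). Part of the level is chance, since the median fell from 12.8% in the libraries used for choosing to 6.61% in the one left out. Stable differences in conversion between cytosines stay open. Of the 689 weak candidates, 457 were still called with a beta-binomial background, but this count cannot decide. A wider fitted spread also absorbs true methylation. In the other direction, the 3 p-values were combined as independent, so a difference that the libraries share is not held in this background. No biological explanation was tested.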

How the results depend on the processing

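The count of candidates, 775 as reported, was 489 and 118 at coverage minimums of 20 and 50, 3322, 86 and 15 at level minimums of 5%, 20% and 50%, 109 with the highest of the 3 p-values, and 299 with Bonferroni adjustment; these settings ask for more or less by construction. It stayed within 1.5 times under the coverage minimum of 5 (822), the Poisson test (733), the beta-binomial test (543), the local background (597) and isolated candidates alone (628). Without replicates 1, 2 and 3 it was 772, 754 and 825, but only 472, 455 and 483 of the 775 were among them. Of the 20 sites with the highest share, all were called with the Poisson and beta-binomial tests, the local background, Bonferroni adjustment and each replicate left out, 19 with the highest p-value, 18 as isolated candidates and 15 at a level minimum of 50%; at coverage minimums of 20 and 50 only 14 and 6 had a value, and these were called. The background was 1.30% as the median of cytosines read at least 50 times, and the mean r between libraries, 0.0877, was 0.266 at that coverage and 0.0813 without sites above 50%. The odds ratio for the CTCCA spacing was 0.525, 0.596 and 0.468 (no longer past the threshold) at a coverage minimum of 20, a level minimum of 20% and the highest p-value; that for the CNGGG spacing was 1.18 at a coverage minimum of 20. For ribosomal proteins it was 2.10 at that minimum and 2.25 for isolated candidates, and for methyltransferases and readers 0 at a level minimum of 20%, 3.83 for isolated candidates and 4.11 to 6.81 with 1 replicate left out (lowest without replicate 3). Among lists that passed no test, the odds ratio crossed 1 for pluripotency (2.61 at a level minimum of 20%, 2.05 with the highest p-value, 1.07 for isolated candidates, 0.847 to 1.53 with 1 replicate left out), cytoskeleton (0.613 at a coverage minimum of 20, 0 at a level minimum of 20%, 0.570 to 0.626 with 1 replicate left out), glycolysis (0.592 at a coverage minimum of 20, 0 with the highest p-value), translation factors (2.60 with the highest p-value), early differentiation (0 to 1.48 with 1 replicate left out) and imprinted genes (0 to 1.85). The cause was not tested. Of 97 alternative values for gene lists, 78 kept direction and side of the threshold, 4 lost the call in the same direction and 15 changed direction, 1 of which (methyltransferases and readers) also lost the call; of 14 for the spacings, 10 kept both and 4 lost the call; all 6 for clustering kept both. No paired analysis was possible because there is 1 group. The chrM background was not run because no mitochondrial transcript was analysed. Depth and the level minimum of 10% both limit what could be called: 32% of simulated sites at 10% were recovered, and 88% at 20%. A site set at 10% can fall below that minimum at any depth, and the simulation does not separate depth from the minimum.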

Other observations

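The position bins, the offsets and the depth limit in this part were chosen after the data were seen. Candidates were more frequent at low transcript positions than other testable cytosines. Positions were pooled over all transcripts, without matching on transcript length or coverage. Runs of candidates that share reads count as independent here, so the p-values by position are too small. Candidates without a neighbour were not tested alone. The first 200 nt held 20.9% of candidates and 10.6% of other cytosines (odds ratio 2.24, adjusted p = 2.53e-16, Fisher's exact test over cytosines). By the same exact test, positions 201 to 500 held 22.6% and 14.8% (odds ratio 1.67, adjusted p = 2.06e-08), and positions beyond 2000 held 22.1% and 31.3% (odds ratio 0.621, adjusted p = 2.06e-08). The unconverted share of the other cytosines fell along the same bins, from 1.49% ± 0.0693 in the first 200 nt to 1.42% ± 0.0581 beyond 2000 nt (SD, n = 3). Around all 775 candidates, cytosines were fewer at offset -3 (20.5% against 27.5% of other sites, odds ratio 0.680, adjusted p = 0.000183) and at -2 (18.8% against 23.1%, odds ratio 0.773, adjusted p = 0.0485), by Fisher's exact test adjusted over 20 offsets, and no other offset passed. Around the 628 candidates without a neighbouring candidate, the deficit passed at 5 offsets (-3, -2, -1, +2 and +3), but leaving out candidates with a neighbour removes sites that have a cytosine nearby, so part of that deficit is built in.

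Among candidates at 20% or above, 10 had a mean coverage of at least 100 reads. Besides those in Nus1, Cenpv, Sec61a1, Rpl18 and 2 in Brip1 (positions 4228 and 4231), they lay in Eif4ebp1, the translation repressor 4E-BP1, with 29.4% ± 1.89 at position 567 (433 of 1474 reads), in Hnrnph1, a splicing regulator, with 24.3% ± 3.58 at position 1307 (175 of 718 reads), in Atn1, a transcriptional corepressor, with 24.1% ± 1.63 at position 2806 (78 of 325 reads), and in Cdca4 with 23.7% ± 2.12 at position 2077 (189 of 798 reads; SD, n = 3 for each).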
